A study of Homo sapiens with 13 samples.

How the data were processed

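RNA, KAP1 binding, H3K9me3 and H3K4me1 were measured in H1 cells, an established line of human embryonic stem cells. KAP1 is the protein made from TRIM28, a corepressor that zinc finger proteins bring to DNA. The 13 samples fell into 11 groups by their labels. Polyadenylated cytoplasmic RNA was sequenced from 3 cultures at passage 59, taken 15 days after transduction with a lentiviral vector that carried no hairpin (sh-empty), a nonspecific hairpin (sh-nonspecific) or a hairpin against TRIM28 (sh-TRIM28), with 1 library each. Chromatin immunoprecipitation covered KAP1 in untransduced cells (1 sample at passage 75 with a custom antibody, 1 at passage 69 with a commercial one), H3K9me3 in untransduced cells at passage 75, and H3K4me1 10 days after transduction with sh-nonspecific or sh-TRIM28, with 1 sample each. Input samples were not used here.

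The deposited gene table holds 1 line per RefSeq transcript with an RPKM value for each RNA library, and the deposited repeat table holds an RPKM value per Repbase family and library, per the file headers. The authors also deposited the ratio of each pair of RPKM columns. These ratio columns were checked as quotients of the RPKM columns and otherwise not used. Genome build hg19 and Bowtie 0.12.5 are named in the submitters' processing notes, without a role. The counting method, the read totals and the rule for reads that match several places are not given in the sources used here. The scale of the RPKM values is not stated and the values are small for that unit, so they were read only against each other. The KAP1 and H3K9me3 peak lists hold positions and a score per peak, as deposited by the authors, and their peak names carry the name of the peak caller MACS. The score is the authors' own and served only to rank peaks within a list. The H3K4me1 lists as deposited hold positions only, and their caller and threshold are not given in the sources used here. Each of these lists was called on 1 sample, per the labels. A further KAP1 list belongs to the series as a whole, and the sample or samples behind it are not stated.

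Values of 1 gene or family were whole multiples of a step, to a relative tolerance of 3e-08 in 78.7% of the 18346 genes. A step can be the value of 1 read or of a fraction of 1, since the families L1MA5 and L1MA6 had the same sh-nonspecific RPKM of 0.000113 at 1 and 20 steps. A minimum in steps is therefore no minimum in reads. Comparing steps between libraries gave the relative depth. 1 read was worth 1.17 times as much in sh-nonspecific as in sh-empty and 1.01 times as much in sh-TRIM28, so that equal values rested on 85.8% and 98.5% of the reads in sh-empty. Where a gene had several transcripts, the one with the highest summed value stood for it. Of 38872 lines, 27258 RefSeq identifiers carried a symbol in the table and 418 more were named from a reference gene table of assembly GRCh38.p14, from which no coordinates were taken. The symbols printed are those of the deposited table. For 4 of the 58 genes named by rule, the reference gene table gives the transcript another symbol.

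Libraries were scaled by the trimmed mean of log ratios to sh-empty over genes, leaving out 30% at each end. The factors were 0.989 for sh-empty, 0.981 for sh-nonspecific and 1.03 for sh-TRIM28. Ratios are differences of log2(scaled value + pseudocount), with the median step as pseudocount (0.000146 for genes, 0.000183 for families), and every fold printed is on that scale, which understates the change of low genes. Tests kept genes with a highest value of at least 10 times the median step and, where a common step was found, at least 10 steps in 1 library. Families needed at least 10 steps in 1 library, or 10 times the median step if above 0 in 1 library only. Families without a common step were kept with no minimum. This left 14886 genes and 115 of 267 named families.

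The size rule called a gene or family higher or lower with sh-TRIM28 when it differed at least 2-fold, in the same direction, from sh-empty and from sh-nonspecific. The same rule with each control library in the place of the knockdown gave reference counts. The plan, made for a table of counts, added counting intervals to this rule and a count-based test with both control libraries as 1 arm. Since the values are RPKM, the rule was applied without intervals, and limma 3.58.1 in R 4.3.3 on the log2 values replaced the count-based test, with Benjamini-Hochberg adjustment. That fit has 1 residual degree of freedom and assumes that the lone knockdown library varies like the controls. Each gene list or repeat list was described by the percentile of its median among 10000 random lists of the same size matched on expression, in 10 classes for genes and 3 for families. A list was called when its median lay outside the central 95% of the random lists, on the same side, against both controls. The 17 gene lists and 13 repeat lists, the size rule, the named-gene rule and the alternatives, other than those said to be chosen after seeing the data, were fixed before the data were examined.

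Named genes are TRIM28, the 12 higher and the 12 lower genes with the largest smaller one of the absolute log2 ratios among genes with at least 50 steps in 1 library, up to 4 members of each list past the size rule (or its 2 most abundant members where none was), the 10 families higher and lower by the same order, and the 5 highest scoring peaks of each comparison of peak lists. Genes or peaks outside this rule are said to be chosen after their values were seen. Some genes that the rule names are not reported here.

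Peaks counted as overlapping when they shared at least 1 bp. Shares of peaks carry Wilson 95% intervals, which cover counting error only, and stand beside the mean over 100 random placements of the peaks within their chromosomes. Gene starts were taken from the positions in the deposited gene table and measured to the nearest peak. The number of called genes in each distance class was set beside 10000 permutations of the classes among genes of like expression. Genes are not replicates, so these permutations describe the libraries at hand. They also treat neighbouring genes as independent. Read depths of the immunoprecipitated libraries are not given in the sources used here, so a peak missing from a list is not shown to be absent.

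The statistics were tested on simulated data, made from the values of the 14886 tested genes with 200 genes changed. Noise was normal, with a spread per class of expression taken from the median absolute deviation of the ratio between the controls. It held no outlying genes and no library effects, so the simulated calls are not error rates for the real libraries. There the size rule called 280 genes with sh-nonspecific and 106 with sh-empty as the lone library. For the comparison of sh-TRIM28 with both controls, the size rule recovered 78 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 3, and called 99 unchanged genes. In the same simulation limma recovered 12 of 100 and 98 of 100, and called 0 unchanged genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps. Alternatives covered the scaling, the minimum, the fold, the pseudocount, each control library left out, the overlap that counts, the peak score, an extension of peaks and the KAP1 list.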

Results

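RNA levels, KAP1 binding, the repressive mark H3K9me3 and the enhancer mark H3K4me1 were compared in H1 human embryonic stem cells with and without knockdown of TRIM28. TRIM28 encodes KAP1, a corepressor that zinc finger proteins carry to endogenous retroelements and that recruits an H3K9 methyltransferase. RNA came from 3 libraries, 1 each from cells 15 days after transduction with sh-empty, sh-nonspecific or sh-TRIM28, so that no RNA difference has a replicate check. Equal values rested on 85.8% as many reads in sh-nonspecific and 98.5% in sh-TRIM28 as in sh-empty. Genes above 0 numbered 17634, 17527 and 17627 in sh-empty, sh-nonspecific and sh-TRIM28, and the sums of RPKM over transcripts were 4603, 4728 and 4397. The 18S ribosomal RNA RN18S1, which polyadenylated RNA should hold little of, had RPKM values of 62.0, 24.95 and 11.3 in the same order. The peak lists held 57810 KAP1 peaks from the first untransduced sample, 25306 in the KAP1 list given for the series, 76032 for H3K9me3, 107526 for H3K4me1 with sh-nonspecific and 100488 for H3K4me1 with sh-TRIM28. All positions are on genome build hg19.

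TRIM28 itself fell in the sh-TRIM28 library, which checks the labels. Its transcript (chromosome 19, 59055836 to 59062082) had an RPKM of 7.07 in sh-empty, 8.85 in sh-nonspecific and 0.567 in sh-TRIM28. This was 13.0 times lower than in sh-empty and 16.4 times lower than in sh-nonspecific, or -3.70 and -4.03 on the log2 scale. The control libraries differed from each other by 1.26 times. With both controls as 1 arm, limma gave a log2 difference of -3.87 (SE 0.43, adjusted p = 1.68e-16).

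Of 14886 genes tested for the effect of the knockdown, 237 were at least 2-fold higher with sh-TRIM28 than in both control libraries and 378 were at least 2-fold lower. The same rule with sh-nonspecific in the place of the knockdown gave 206 higher and 74 lower genes, and with sh-empty 54 higher and 52 lower. The knockdown library stood apart at 615 genes in all, against 280 and 106 for the control libraries, and the gap was wider for lower than for higher genes. With both controls as 1 arm, limma called 179 higher and 355 lower genes at a false discovery rate of 0.05, against 1 higher and 0 lower with sh-nonspecific as the lone library and 35 higher and 10 lower with sh-empty as the lone library. These fits pooled the spread differently, with infinite prior degrees of freedom for sh-TRIM28 and sh-empty and 2.79 for sh-nonspecific, so their counts are not on equal terms. At an unadjusted p under 0.05 they held 1622, 1061 and 203 genes. Without sh-empty the size rule gave 1803 genes and without sh-nonspecific 900, and limma without the minimum on low values called 0 genes at the false discovery rate and 1531 at the unadjusted p.

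**Figure D1:**
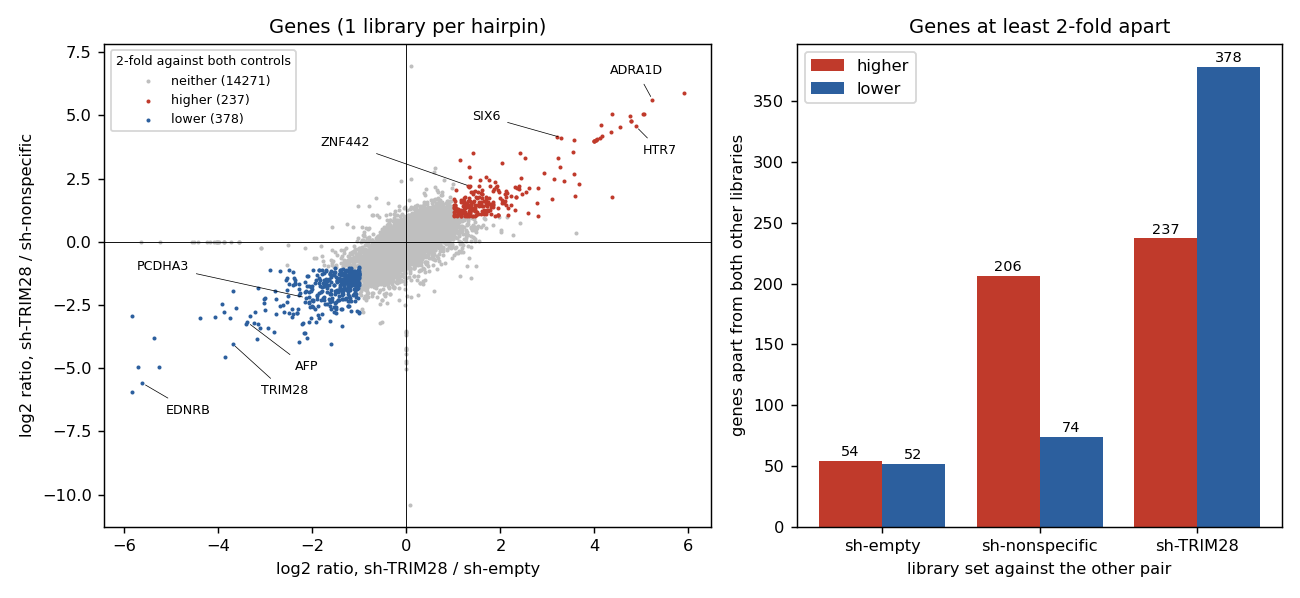
Left, log2 ratio of each of 14886 genes with sh-TRIM28 against sh-empty (x axis) and against sh-nonspecific (y axis), with the 237 genes at least 2-fold higher than both controls in red, the 378 lower in blue and the other 14271 in grey. Right, number of genes at least 2-fold higher or lower in each library than in both others (1 library per group, no error bars), which was 54 and 52 for sh-empty, 206 and 74 for sh-nonspecific, and 237 and 378 for sh-TRIM28.

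Receptor genes that were barely detected in the controls led the genes that rose. ADRA1D, an alpha-1 adrenergic receptor (chromosome 20, 4201329 to 4229721), was 37.6 times higher with sh-TRIM28 than in sh-empty and 49.1 times higher than in sh-nonspecific, from RPKM values of 0.000555 and 0.000388 to 0.0273. HTR7, a serotonin receptor (chromosome 10, 92500580 to 92617455), was 29.5 and 23.7 times higher. ORM1, an acute phase plasma protein (chromosome 9, 117085336 to 117088755), was 17.5 and 24.8 times higher, but its reads may be shared with the near-identical ORM2. On chromosome 8 the gene listed as OC90 (133073733 to 133123406; HHLA1 in the reference gene table) was 11.8 and 16.4 times higher, and the overlapping gene listed as AC100868.1 (133036467 to 133097902; OC90 in the reference gene table, a protein of the inner ear) was 11.9 and 6.48 times higher. The eye field transcription factor SIX6 (chromosome 14, 60975869 to 60978529) was 9.81 and 17.4 times higher. Further genes of this group were ARRB1, which encodes a beta-arrestin (9.37 and 10.0 times), the orphan receptor GPR50 (9.56 and 7.86 times), SHISA3 (7.56 and 6.62 times), C20orf103, also named LAMP5 (5.76 and 9.95 times), and AHSP, a chaperone of alpha globin (8.85 and 5.58 times). In the limma fit every gene had the same SE of 0.43 on the log2 scale, since the spread was pooled over all genes. These genes were chosen for large ratios, so that they passed limma followed from the choice and adds no separate support.

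Besides TRIM28, the genes that fell furthest included a receptor, secreted proteins and metabolic enzymes. EDNRB, the endothelin B receptor (chromosome 13, 78469616 to 78493903), was 49.1 times lower than in sh-empty and 48.2 times lower than in sh-nonspecific, from RPKM values of 0.0311 and 0.0302 to 0.000512. AFP, the fetal plasma protein alpha-fetoprotein (chromosome 4, 74296855 to 74321891), was 10.4 and 9.09 times lower, and the chemokine genes CXCL3 (74902306 to 74904524) and CXCL1 (74735110 to 74736959) on the same chromosome were 8.92 and 9.53 times and 14.8 and 6.83 times lower. CXCL1 was also at least 2-fold higher in sh-empty than in both other libraries. The gastrin-releasing peptide receptor GRPR was 13.5 and 8.18 times lower, the synaptic vesicle gene SYT4 10.1 and 7.55 times, and the neuronal membrane gene SLITRK1 7.01 and 11.8 times. AASS, an enzyme of lysine breakdown (chromosome 7, 121715701 to 121784334), was 8.10 and 6.50 times lower, from RPKM values of 0.962 and 0.766 to 0.124. IDO1, an enzyme of tryptophan breakdown (chromosome 8, 39759794 to 39785963), was 6.08 and 6.91 times lower, from 0.318 and 0.358 to 0.0543. RMRP, the RNA of the RNase MRP complex, was 9.39 and 6.88 times lower, and SNORD116-9, a small nucleolar RNA of an imprinted cluster, was listed at 0 with sh-TRIM28 and at RPKM values of 0.00544 and 0.00427 in the controls. These last RNAs are not polyadenylated, and RN18S1, which is not either, was also lowest with sh-TRIM28. These genes too were chosen for large ratios, so with the same SE for every gene their passing limma adds no separate support.

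Among the lists of stem cell and lineage genes, pluripotency genes lay lower as a group. The 26 pluripotency genes had a median log2 ratio of -0.28 against sh-empty and -0.42 against sh-nonspecific, with 16 lower and 4 higher than in both controls, and the list was called as lower against both. By the size rule 3 fell. Among them DPPA2, a chromatin protein of early embryo cells, was 3.85 and 3.07 times lower and the growth factor FGF4 2.58 and 3.19 times lower. FGF4 was low, with RPKM values of 0.00388 and 0.0048 in sh-empty and sh-nonspecific and 0.00148 with sh-TRIM28. The core factors POU5F1, NANOG and SOX2, chosen after their values were seen, did not pass the rule. Their RPKM values in sh-empty, sh-nonspecific and sh-TRIM28 were 4.45, 5.30 and 3.78 for POU5F1, 0.397, 0.293 and 0.370 for NANOG, and 0.442, 0.553 and 0.320 for SOX2. Of 12 naive and preimplantation genes, DPPA5 (9.03 and 14.2 times), CCNA1 (4.45 and 3.95 times) and NLRP7 (2.56 and 4.73 times) fell, with list medians of -0.24 and -0.56 that were not called. These were low too, with DPPA5 at RPKM values of 0.00967 and 0.0152 in sh-empty and sh-nonspecific and 0.000981 with sh-TRIM28. The 8 trophoblast genes had medians of -0.57 and -1.40, called as lower, but they were also higher in sh-nonspecific than in sh-empty by a median of 0.90. In that list only the hormone subunit CGB5 fell (2.26 and 5.03 times). It shares sequence with near-identical copies and was also at least 2-fold higher in sh-nonspecific than in both other libraries. With the alternative minimum of 50 steps, too few members of the list were left to repeat its call.

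Lineage genes moved both ways and none of their other lists was called. Of 12 neuroectoderm genes, SIX6, the forebrain factor LHX2 (4.24 and 2.88 times) and the adhesion gene NCAM1 (2.62 and 2.36 times) rose, while the neural crest factor SOX10 (2.64 and 2.79 times) and the microtubule gene MAP2 (2.89 and 2.06 times) fell, with list medians of 0.27 and 0.10. MAP2 was named after its values were seen. Of 9 mesoderm genes, with medians of -0.14 and -0.27, EOMES rose 5.35 and 11.4 times and ISL1 fell 3.35 and 2.32 times, and EOMES was also at least 2-fold lower in sh-nonspecific than in both other libraries. Of 6 endoderm genes, with medians of -0.33 and -0.04, 1 rose and 1 fell, the latter being AFP. Markers of cell types that could be mixed in gave no call either. None of the 8 fibroblast genes passed the rule (medians 0.02 and 0.00), with RPKM values in sh-empty, sh-nonspecific and sh-TRIM28 of 1.71, 1.65 and 1.97 for THY1 and 0.668, 2.02 and 0.516 for COL1A1, which was at least 2-fold higher in sh-nonspecific than in both other libraries. Of 6 blood and endothelial genes (medians -0.45 and -0.74), the angiopoietin receptor TEK fell 5.69 and 7.07 times.

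Clustered protocadherins, neuronal adhesion genes in tandem arrays on chromosome 5, lay lower with sh-TRIM28. Of 52 measured, 44 were lower than in both controls and 2 higher, with medians of -0.51 and -0.88, below all 10000 random lists against each control. PCDHA3 (4.398 and 4.63 times), PCDHGA1 (3.25 and 2.91 times), PCDHB15 (2.80 and 2.89 times) and PCDHGB1 (2.29 and 2.84 times) led the 7 that fell. The alpha and gamma genes share their last exons, so their values are not independent. In sh-nonspecific the list lay above sh-empty by a median of 0.31.

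ZNF-named zinc finger genes, many of which encode proteins that bind KAP1, lay slightly higher. The 468 measured had medians of 0.08 against sh-empty and 0.40 against sh-nonspecific, with 253 higher than in both controls and 102 lower, and the list was called as higher. By the size rule 9 rose, led by ZNF846 (2.99 and 2.98 times), ZNF442 (2.57 and 4.56 times) and ZNF878 (2.53 and 3.33 times) on chromosome 19, and 3 fell, led by ZNF528 (5.33 and 3.31 times). The list lay lower in sh-nonspecific than in sh-empty by a median of -0.33. Its call ended with the alternative minimum of 50 steps, although the smaller of its medians stayed at 0.08. Of 31 genes for partners of TRIM28 and heterochromatin proteins (medians -0.01 and 0.07), only TET2, which oxidises methylated cytosine, passed the rule and rose 2.34 and 3.32 times.

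The remaining gene lists were not called. Of 24 imprinted genes (medians -0.10 and -0.12), MAGEL2 fell 3.74 and 4.41 times. Interferon response genes had medians of 0.34 against sh-empty and 0.19 against sh-nonspecific over 25 genes, at percentiles 99.99 and 84.4 of random lists, and the viral RNA sensor OAS3 rose 3.01 and 2.13 times. The list was also 0.34 higher in sh-nonspecific than in sh-empty. None of 20 genes of the p53 response passed the rule (medians 0.19 and -0.07), and 4 were at least 2-fold higher in sh-nonspecific alone. Its most abundant members had RPKM values in sh-empty, sh-nonspecific and sh-TRIM28 of 0.638, 0.876 and 0.637 for AEN and 0.384, 0.311 and 0.405 for TRIAP1. Of 17 germline and cancer-testis genes (medians -0.08 and -0.02), TDRD1, which acts with piRNAs, fell 2.90 and 3.24 times. Of 20 stress and immediate early genes (medians -0.12 and -0.31), JUN fell 2.54 and 2.75 times and IER3 rose 2.43 and 2.05 times. None of 23 cell cycle genes passed the rule (medians -0.07 and -0.02), with RPKM values in the same order of 2.17, 2.01 and 2.05 for MCM3 and 1.85, 2.10 and 1.83 for MCM5.

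Repeat families, the subject of the series, were more often higher than lower with sh-TRIM28, when each family counted alike whatever its level. The RPKM summed over all named families, before scaling, was lower with sh-TRIM28 (14.15) than in sh-empty (15.96) and close to sh-nonspecific (13.87). Of the families tested, 81 were higher than in both controls and 14 lower, with a median log2 ratio of 0.25 against sh-empty and 0.54 against sh-nonspecific. The control libraries differed in the same range, with a median of -0.22 for sh-nonspecific against sh-empty. By the size rule 10 families rose and 1 fell, against 0 higher and 7 lower in sh-nonspecific alone and 0 and 2 in sh-empty alone. HERVIP10FH, an endogenous retrovirus of class ERV1, was 2.73 and 3.10 times higher, from RPKM values of 0.00161 and 0.00139 to 0.00491, and HERVK11I, of class ERV2, was 2.32 and 3.05 times higher, from 0.00289 and 0.00214 to 0.00724. Further ERV1 families that rose were MER4E (2.60 and 2.67 times), HERVE (2.27 and 2.10 times) and MER4A1_LTR, which was 2.84 times higher than in sh-empty and listed at 0 in sh-nonspecific. The L1 families were L1PA15 (2.43 and 3.64 times), L1MA4 (4.75 and 4.49 times) and L1MB3, which was 3.03 times higher than in sh-nonspecific and listed at 0 in sh-empty. L1MA4 rose to an RPKM of 0.00119 from control values of 9.76e-05 and 0.000113, which lie below the pseudocount of 0.000183. Among DNA transposons, CHARLIE9 was 2.88 and 2.12 times higher, and MER1A was 2.26 times higher than in sh-empty and listed at 0 in sh-nonspecific. HERV4_I, of class ERV1, was 2.83 and 3.17 times lower. A step can be a fraction of a read, so the number of reads behind each family is not known. With at least 50 steps required, 5 families were higher and 1 lower, and without sh-empty the rule gave 27 higher and 2 lower. With the median of all families set equal across libraries, an alternative chosen after seeing the data, 5 were higher and 2 lower.

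By class, 24 of 29 ERV1 families were higher than in both controls, with medians of 0.38 and 0.93, and so were 27 of 31 L1 families (0.33 and 0.54), 12 of 17 ERV2 families and 6 of 11 ERV3 families. The HERVH and LTR7 list, a retrovirus with high expression in human embryonic stem cells, was the only repeat list called and lay lower, with medians of -0.48 and -0.34 over 4 families, none of which passed the rule. Its members, whose values were picked out after being seen, had log2 ratios against sh-empty and sh-nonspecific of -0.61 and -0.77 for LTR7B, -0.59 and -0.52 for LTR7A, -0.37 and -0.15 for LTR7Y, and -0.34 and 0.12 for HERVH. That call ended with at least 50 steps required, although the smaller of the medians stayed at -0.34. The 17 HERVK families had medians of 0.27 and 0.47, the 7 HERV9 and LTR12 families 0.25 and 0.93 with 7 of 7 higher than in both controls, and the 6 of HERVS71, HERVW and HERVE 0.09 and 0.43. Young primate L1 (10 families) had 0.20 and 0.53, older primate L1 (10 families) 0.52 and 0.79, mammalian L1 (8 families) 1.08 and 0.39, ERVL and MaLR (9 families) 0.27 and 0.61, and DNA transposons (7 families) 0.10 and 0.74. SVA had 1 family, at -0.11 and 0.02, and 0 families of AluY, of AluS and AluJ, and of satellites were tested. Random lists were drawn from all tested families, members of the list included, so these lists were compared with repeats and not with genes.

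**Figure D2:**
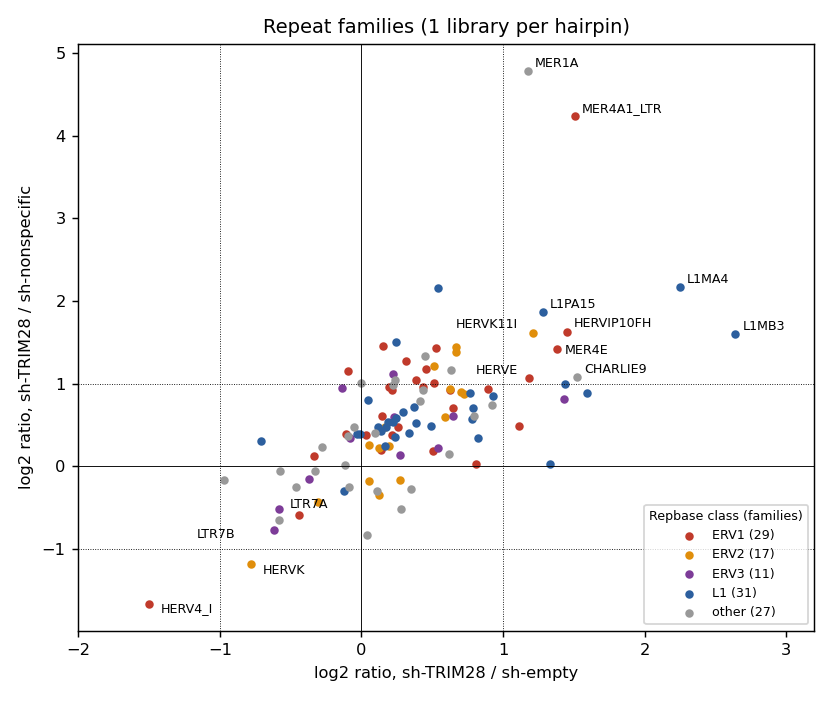
Log2 ratio of each tested repeat family with sh-TRIM28 against sh-empty (x axis) and against sh-nonspecific (y axis), coloured by Repbase class (ERV1 29 families, ERV2 17, ERV3 11, L1 31, other 27), 1 library per group and no error bars. Dotted lines mark a 2-fold difference, MER1A, MER4A1_LTR and L1MB3 are placed by the pseudocount where a control was listed at 0, and 81 families lie above 0 on both axes against 14 below.

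KAP1 and H3K9me3 peaks coincided in untransduced cells far more than random placement gave. Of 57810 KAP1 peaks, 19973 or 34.5% overlapped an H3K9me3 peak (34.2 to 34.9, Wilson 95%), against 5.20% at random, a 6.64-fold excess. Of 76032 H3K9me3 peaks, 26.4% overlapped KAP1, against 4.06% at random. The highest scoring KAP1 peak on H3K9me3 (chromosome 17, 5712590 to 5713401) lay 224758 bp from the nearest gene, NLRP1. The next ones lay on chromosome 7 (46508175 to 46509059), within MAP4K3 on chromosome 2 (39586150 to 39588180), on chromosome 10 (55154820 to 55155935) and within DOCK4 on chromosome 7 (111436431 to 111437449). The highest scoring peak off H3K9me3 (chromosome 21, 39595620 to 39596384) lay 32279 bp from KCNJ15, and another of the 5 highest lay within CMPK2 (chromosome 2, 6985151 to 6986051). The highest scoring H3K9me3 peak off KAP1 lay within MCF2L (chromosome 13, 113640466 to 113644835). Exons and introns were not annotated. With the KAP1 list given for the series, 57.7% of 25306 peaks overlapped H3K9me3 (57.0 to 58.3), against 5.04% at random, an 11.4-fold excess.

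The KAP1 lists shared many positions. Of the peaks in the list of the first sample, 29.6% (29.2 to 30.0) overlapped the list given for the series, against 1.35% at random, and of the latter 69.04% (68.5 to 69.6) overlapped the former, against 3.12%. The shared peaks included the one near NLRP1 and the one within MAP4K3, while peaks within LPCAT1 (chromosome 5, 1455897 to 1457202), ZNF665 (chromosome 19, 53687926 to 53688795) and SYNE1 (chromosome 6, 152811784 to 152812849) were among the highest scoring of the first list with no counterpart. Which sample the series list came from is not stated, so the overlap is not a measure of replicate agreement.

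Most H3K4me1 peaks were found with both hairpins. Those seen with sh-TRIM28 only numbered 24114, or 24.0% of that list (23.7 to 24.3), and those seen with sh-nonspecific only 32157, or 29.9% (29.6 to 30.2). KAP1 sites were more common among the former. Of peaks seen with sh-TRIM28 only, 12.6% overlapped a KAP1 peak (12.1 to 13.0), against 6.45% of those seen with sh-nonspecific only (6.19 to 6.72), and 8.13% against 2.83% overlapped H3K9me3. Peaks in a single list were narrower, with median widths of 392 bp with sh-TRIM28 only and 410 bp with sh-nonspecific only, against 795 and 883 bp for the other peaks of these lists. The comparison is of 2 libraries with 1 sample each, and their depths are not given in the sources used here.

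At KAP1 sites on H3K9me3, H3K4me1 was more frequent after the knockdown. Of the 19973 such sites, 4.73% had an H3K4me1 peak with sh-nonspecific (4.45 to 5.03) and 9.50% with sh-TRIM28 (9.10 to 9.92), against 7.12% and 6.50% for random placement. An H3K4me1 peak was present with sh-TRIM28 only at 1250 sites (6.26%) and with sh-nonspecific only at 297 (1.49%), a ratio of 4.21. At the 37837 KAP1 sites off H3K9me3 the shares were 20.7% and 20.6%, with 1846 sites against 1913, a ratio of 0.965. The highest scoring KAP1 peaks with H3K4me1 in the knockdown only were the one within MAP4K3, one 55272 bp from DYNC1I2 (chromosome 2, 172487456 to 172488647), one 3074 bp from PGRMC2 (chromosome 4, 129186354 to 129187323), one 16330 bp from OPA1 (chromosome 3, 193431942 to 193433209) and one 7812 bp from NR5A2 (chromosome 1, 200154364 to 200155850). Those with H3K4me1 in the control only were led by a peak within GALK2 (chromosome 15, 49556590 to 49558075). Split into 5 groups of like size by KAP1 score, the share of sites on H3K9me3 with H3K4me1 in the knockdown only was 3.85, 4.91, 6.41, 6.98 and 9.14% from the lowest to the highest scoring group, and in the control only 3.05, 2.28, 1.20, 0.526 and 0.376%. With the KAP1 list given for the series the share on H3K9me3 went from 0.829% to 5.69%, with 733 sites against 24, and off H3K9me3 from 4.61% to 8.52%, with 525 sites against 106, so there the excess was not limited to H3K9me3.

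**Figure D3:**
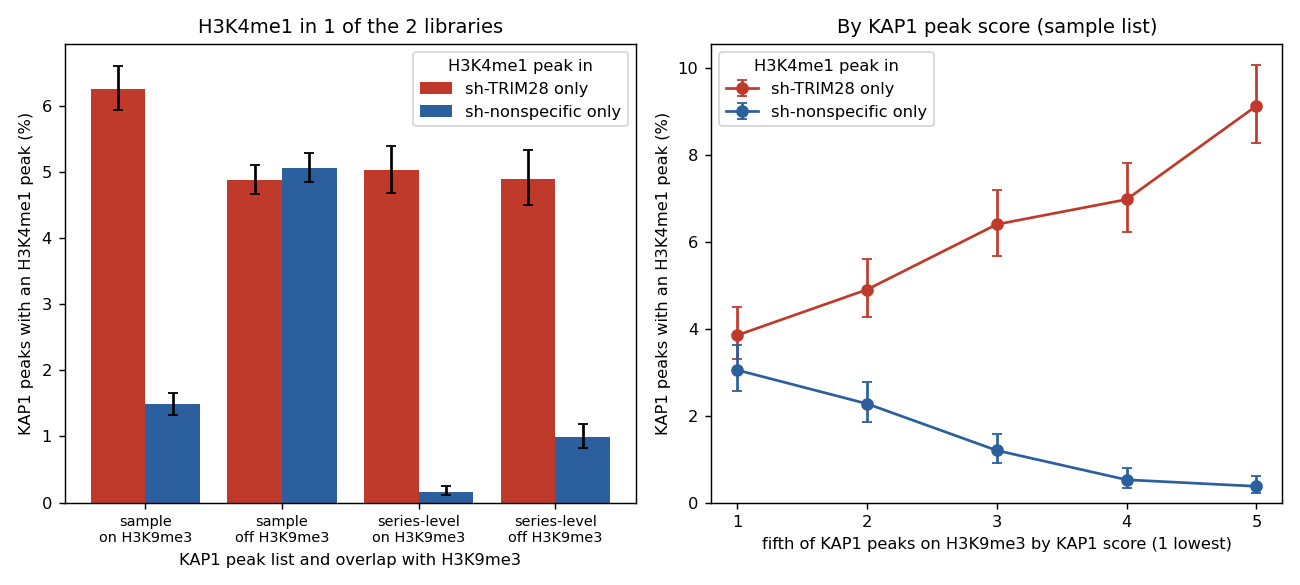
Left, percent of KAP1 peaks with an H3K4me1 peak in the sh-TRIM28 list only or in the sh-nonspecific list only, for the KAP1 list of the first sample and the one given for the series, on and off H3K9me3. Right, the same shares for KAP1 peaks of the first sample on H3K9me3 in 5 groups by KAP1 score, rising from 3.85 to 9.14% for sh-TRIM28 only, with Wilson 95% intervals as error bars in both panels (1 sample per list).

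With the KAP1 list of the first sample, genes that start near a peak rose somewhat more often and genes far from one less often. Of 396 genes that start within 1 kb of a KAP1 peak, 14 rose (3.54%, 2.12 to 5.85), against 2.07% when distances were permuted among genes of like expression, and 335 of 10000 permutations gave as many. Of 1316 genes more than 100 kb away, 9 rose (0.684%, against 1.32%) and 45 fell (3.42%, against 2.19%), which 14 permutations reached. Of the same genes 26 were higher in sh-nonspecific alone (1.98%, against 1.17%), which 48 permutations reached, so the far genes also differed in a control library. Without sh-empty the shares that rose were 5.56% within 1 kb and 1.29% beyond 100 kb, and without sh-nonspecific 5.05% and 1.52%. Distances to H3K4me1 peaks seen with 1 hairpin only gave further differences. Within 1 to 10 kb of those seen with sh-TRIM28 only, 69 of 3643 genes rose (1.89%, against 1.34%), which 6 permutations reached, but within 1 kb only 31 of 2213 did (1.40%, against 1.481%). Near those seen with sh-nonspecific only, 50 of 1162 genes within 1 kb fell (4.30%, against 2.75%), which 3 permutations reached, and 102 of 2636 genes within 1 to 10 kb fell (3.87%, against 2.62%), which 0 permutations reached. In the latter class genes higher in sh-nonspecific alone were in excess too, with 51 of 2636 (1.93%, against 1.45%), which 137 permutations reached, while within 1 kb they numbered 17 of 1162 (1.46%, against 1.53%). With the KAP1 list given for the series, 7 of 261 genes rose within 1 kb (2.68%, against 1.95%), which 2444 permutations reached, and 1.68% beyond 100 kb (against 1.53%), but at 50 to 100 kb only 33 of 3439 did (0.960%, against 1.45%), and 9982 permutations gave as many. These counts were not adjusted for the number of distance classes and peak lists examined, and genes are not replicates. The permutations also moved genes 1 by 1, while called genes lay side by side more often than a permuted gene order gave. Genes that fell formed 48 adjacent pairs, against a mean of 9.45. Neighbours can share a peak, so the counts of permutations can make an excess look rarer than it is.

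H3K4me1 peaks seen with sh-TRIM28 only that lay on both KAP1 and H3K9me3 had more risen genes around them in 2 of the distance classes. Within 1 to 10 kb 6 of 108 genes rose (5.56%, against 1.36% permuted), which 25 of 10000 permutations reached, and within 20 to 50 kb 17 of 503 rose (3.38%, against 1.44%), which 16 reached. At 10 to 20 kb 4 of 156 genes rose (2.56%, against 1.56%), which 2236 permutations reached, and at 50 to 100 kb 13 of 738 (1.76%, against 1.58%), which 3776 reached. Within 1 kb 1 of 17 genes rose, which 3053 reached. Beyond 100 kb fewer rose than permuted, with 186 of 13119 (1.42%, against 1.55%), and 9999 permutations gave as many. Genes higher in sh-nonspecific alone numbered 2 at 1 to 10 kb and 6 at 20 to 50 kb. The genes that rose within 20 kb of such a peak, chosen after their values were seen, included AC100868.1 at 556 bp, ORM2 at 1940 bp (20.8 and 33.6 times higher) and ORM1 at 4086 bp. Others were IRAK2, a kinase of interleukin-1 signalling, at 4407 bp (3.25 and 3.46 times), TMEM106C at 5720 bp (3.42 and 4.67 times), the histamine receptor HRH2 at 6761 bp (3.85 and 2.53 times) and LRRC36 at 8297 bp (4.99 and 4.54 times). The peptide transporter SLC15A1 at 13644 bp was 3.44 and 2.38 times higher, and ALDH1L2, an enzyme of mitochondrial folate metabolism, at 10349 bp was 3.33 and 2.84 times higher. ORM1 and ORM2 are neighbours with near-identical sequence and count as related, not independent, cases. The permutations counted such neighbours apart, so here too they can make an excess look rarer than it is.

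**Figure D4:**
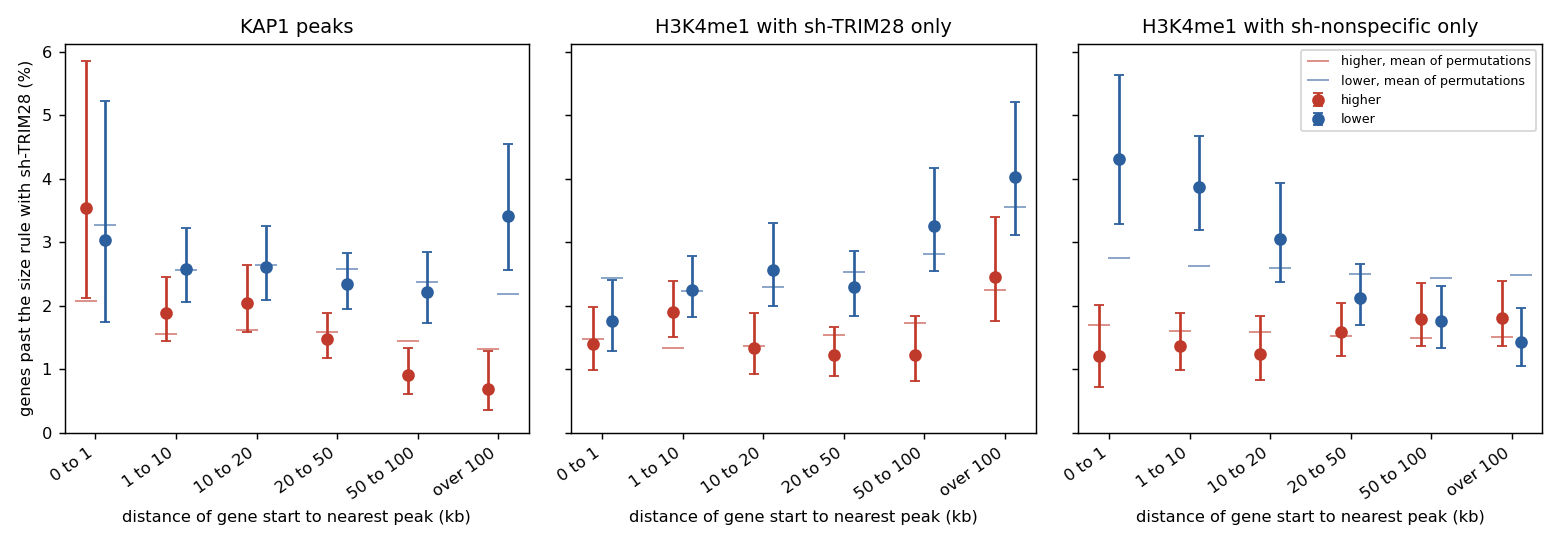
Percent of genes at least 2-fold higher or lower with sh-TRIM28 than in both controls, by distance of the gene start to the nearest KAP1 peak of the first sample, H3K4me1 peak seen with sh-TRIM28 only, or H3K4me1 peak seen with sh-nonspecific only. Points carry Wilson 95% intervals and dashes mark the mean of 10000 permutations of the distance classes, and 102 of 2636 genes (3.87%) were lower at 1 to 10 kb from H3K4me1 peaks seen with sh-nonspecific only, against 2.62% permuted.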

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

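The test among genes far above the value of 1 read and the test of exchanged labels were chosen only after the result was seen, and those of the most abundant genes and of trends before.

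Transcripts with no gene symbol, which no comparison of the report used, also stood apart with sh-TRIM28. Of 10703 such transcripts 6359 passed the minimum, and 285 were at least 2-fold from both controls (90 higher, 195 lower), above the 219 in sh-nonspecific alone (163 higher, 56 lower) and the 69 in sh-empty alone (12 higher, 57 lower).

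The sh-nonspecific library stood apart from both others at 280 genes, 206 of them higher, among them the p53 response genes CDKN1A, BBC3, PHLDA3 and FDXR and the trophoblast genes CGB, CGB5 and CGB8. Lower depth of that library stays open, since among the 6885 genes with a mean of at least 50 times a large step (above 95% of those of genes with up to 20 steps) 16 were apart in sh-nonspecific and 4 in sh-empty, and among the 4962 most abundant genes 8 against 2, too few to decide. A trend with abundance or step size, a rough guide to transcript length, is argued against for the number apart, since its removal left 92.6% of it (242 before, 224 after), but it may account for part of the excess of higher genes, which went from 181 to 137 while lower ones went from 61 to 87. An exchange of its label with sh-TRIM28 is excluded by TRIM28, which was 1.26 times its sh-empty level there. An effect of the nonspecific hairpin and a difference between cultures stay open and were not tested, since each vector had 1 library.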

How the results depend on the processing

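Alternatives with 5 times the pseudocount or with the median of all repeat families set equal were chosen after seeing the data. TRIM28, the called lists and the ratio of knockdown-only to control-only H3K4me1 sites on H3K9me3 kept their direction where they gave a value. Other results changed side with the KAP1 list given for the series. The share of genes beyond 100 kb that rose went from 0.684% (against 1.32% permuted) to 1.68% (against 1.53%). Off H3K9me3, the ratio of knockdown-only to control-only H3K4me1 sites went from 0.965 to 4.95. The 615 genes apart with sh-TRIM28 became 1162 with no minimum, 333 with at least 50 steps, 1812 at 1.5-fold and 900 to 1803 with 1 control library left out (900 without sh-nonspecific, 1803 without sh-empty). The 11 repeat families became 46 with no minimum, 6 with at least 50 steps, 33 at 1.5-fold, 6 with 5 times the pseudocount, 7 with the median of families set equal (5 higher, 2 lower, against 10 and 1), and 16 to 29 with 1 control left out (16 without sh-nonspecific, 29 without sh-empty). limma went from 534 genes to 0 with no minimum (1531 at an unadjusted p under 0.05, smallest adjusted p 0.533), where 18346 genes entered and the pooled spread no longer had infinite prior weight (prior degrees of freedom 1.71). The 5 called lists became 2 with at least 50 steps (ZNF-named genes and HERVH lost their call with the smaller median as large as before, 0.08 and -0.34, and trophoblast genes gave no value), and 5 to 8 with 1 control left out, where neuroectoderm (0.27), interferon (0.34) and p53 genes (0.19) were called without sh-nonspecific. Of KAP1 peaks, the share on H3K9me3 was 31.3% with 50% of the peak covered, 40.3% in the higher scoring part of each list, 39.3% with peaks extended by 500 bp and 57.7% with the list given for the series. The share of KAP1 peaks in both KAP1 lists was 24.2%, 36.3% and 31.3% with the same coverage, score and extension settings. The share of KAP1 peaks on H3K9me3 with H3K4me1 in the knockdown was 3.80%, 8.88% and 14.3% with these settings and 5.69% with the list given for the series, against 0.712%, 3.18%, 9.23% and 0.829% with sh-nonspecific, and the ratio of sites in the knockdown only to sites in the control only was 14.6, 6.99, 3.17 and 30.5, against 4.21 before. The cause was not tested, apart from the number of genes or families entering. TRIM28 kept its direction, at -3.64 to -3.70 against sh-empty, and the size rule gave 613 genes without scaling, 616 with the median of ratios, 475 with 5 times the pseudocount and 887 with every transcript counted. The H3K4me1 lists hold no score, so their higher scoring part gave no value. A likelihood ratio count test and a second count-based tool were planned and not run, since the values are not counts. No paired analysis was possible because the groups compared had 1 library or 1 peak list each, and the groups that share replicate numbers 1 and 2, KAP1 and input of untransduced cells, were not compared with each other, as the input was not used here. Depth limits low genes and families most, since the minimum rests on 10 steps, which can be fewer reads.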

Other observations

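The tests of called peak numbers, of weak peaks, of a uniform shift and of few reads per family were chosen only after the result was seen, and those of KAP1 score, gene order and zinc finger genes before. The regions and genes named here were chosen after their values were seen.

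Windows of 10 neighbouring genes placed several changes side by side. On chromosome 4, from 73146686 to 74965010, the median of the smaller log2 ratio was -2.005 and 7 of 10 genes fell, a run of chemokine genes next to AFP. CXCL2 was 3.46 and 3.87 times lower, CXCL5 8.03 and 4.65 times and CXCL6 2.62 and 2.18 times, and PF4 was listed at 0 with sh-TRIM28 and at RPKM values of 0.00808 and 0.00869 in the controls. On chromosome 16, from 718086 to 797295, 5 of 10 genes fell (median -0.89), among them FBXL16 (2.84 and 5.21 times), METRN (2.57 and 4.30 times) and HAGHL (2.73 and 4.86 times). On chromosome 19, from 11832135 to 12167127, 10 zinc finger genes had a median of 0.90 and 4 rose. On chromosome 6, from 27782822 to 27860884, 10 histone genes had a median of -0.79 and 3 fell. The same histone window was also among the highest in sh-empty alone (median 0.46, 2 higher), so it differed between the controls as well. Other histone windows on chromosome 6 were among the highest in sh-empty too. RN18S1, which is not polyadenylated, was likewise highest in sh-empty and lowest with sh-TRIM28 (RPKM 62.0 and 11.3). A difference between libraries in the selection of polyadenylated RNA was not told apart from a fall with the knockdown here.

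Single genes moved far in 1 control library. AADAC, arylacetamide deacetylase, had RPKM values in sh-empty, sh-nonspecific and sh-TRIM28 of 4.9e-05, 0.272 and 6.05e-05 (chromosome 3, 151531825 to 151546272). UGT2B10, a glucuronosyltransferase, had 0.0238, 6.26e-05 and 0.0267 (chromosome 4, 69681711 to 69696914).

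More KAP1 sites on H3K9me3 had an H3K4me1 peak with sh-TRIM28 only than with sh-nonspecific only. A larger number of peaks called in the knockdown is argued against, since its H3K4me1 list held fewer peaks (100488 against 107526). The ratio on H3K9me3 was 4.36 times that off H3K9me3 (3.79 to 5.03), but this restates the pattern. With the KAP1 list given for the series the ratio off H3K9me3 was 4.95, so there the excess was not limited to H3K9me3. Weak peaks that come and go at random stay open. The ratio of 4.21 (3.71 to 4.78) lay above the 0.75 of all H3K4me1 peaks, but it is the pattern itself. The H3K4me1 lists hold no score by which weak peaks could be told apart. Loss of KAP1 from its sites may explain it as a hypothesis, since the share was 9.14% in the highest of 5 groups by KAP1 score (8.28 to 10.1) and 3.85% in the lowest. KAP1 peaks were also wider in the highest group (median 1261 bp against 909 bp), which makes any overlap likelier. The share in the control only went the other way, at 0.376% against 3.05%. KAP1 binding was not measured after the knockdown. Different hairpin cultures with 1 library each and an unknown peak threshold stay open and were not tested.

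More repeat families rose than fell with sh-TRIM28. Few reads per family stay open, since of 25 families with a mean of at least 50 times a large step (above 95% of those of families with up to 20 steps) 12 were above both controls and 5 below, too few to decide, and 0 rose or fell by the size rule. A uniform shift of repeat reads against gene reads may account for part of it, since with the median of all families set equal 5 of the 10 were left. That setting would also remove a true rise of most families, so the data do not separate a technical shift from derepression.

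A hypothesis that genes rose in regional runs was tested by gene order. There were 19 adjacent pairs in which both genes rose among 227 risen genes, above all of 1000 permutations (mean 3.54, highest 11). Genes that fell gave 48 pairs (mean 9.45, highest 20), but genes higher in sh-nonspecific alone gave 12 (mean 2.94, highest 11), so the runs may not be particular to the knockdown. Neighbours with near-identical sequence, such as ORM1 and ORM2, add pairs of their own.

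A hypothesis that risen zinc finger genes carry KAP1 on H3K9me3 was tested on the 9 ZNF-named genes that rose, 7 of them on chromosome 19. Of these 7 had such a peak in the gene (77.8%, 45.3 to 93.7), against 197 of 456 ZNF-named genes that did not rise (43.2%, 38.7 to 47.8) and 19.4% of all other genes. The intervals overlap, so 9 genes were too few to decide. Among all ZNF-named genes with a position, the 204 with such a peak had median log2 ratios of 0.16 against sh-empty and 0.56 against sh-nonspecific (7 rose, 2 fell). The 261 without one had 0.02 and 0.27 (2 rose, 1 fell). This difference was not tested.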
